A study of Mus musculus with 6 samples.

How the data were processed

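The series compared prefrontal cortex of 3 wild type and 3 Nrf2 knockout samples from male ICR mice, an outbred stock, aged 3 to 4 months. Nrf2 is the protein made from the gene Nfe2l2, a transcription factor for antioxidant and detoxification genes. The labels give neither the deleted part of the gene nor whether each sample came from a separate animal, so the p-values measure the spread between these samples, which may be technical. Per the labels' protocols, total RNA was purified on columns of a commercial kit and labelled with the dye Cy3 by Agilent's Low Input Quick Amp method. Each sample was hybridised alone to 1 array, and the array held probes for coding transcripts, long non-coding RNAs (lncRNAs) and circular RNAs (circRNAs). CircRNAs are closed loops made by back-splicing, mostly from exons of coding genes.

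The deposited scanner output of each array gives intensity values on a linear scale, made with Agilent Feature Extraction 12.0.3.1 per the file headers, while the submitters' processing notes name version 10.7 and limma. Per the file headers, the processed signal was background-subtracted and spatially and multiplicatively detrended, and low values were replaced by a surrogate. The authors' processed value table was on a log2 scale by comparison with the scanner values: each of its 6 columns correlated with log2 of the processed signal of its array at r of at least 0.99986 across 150305 probes. The absolute difference from quantile-normalised log2 signals had a median of 0.00355 to 0.00432, and the column medians were 5.588 or 5.589. Its probes were not centred, so no direction had to be settled, and the exact steps behind it are not given in the sources used here. It served as an alternative only.

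For the results, log2 of the processed signal minus the 75th percentile of its array was taken for each spot. Control spots (4974) were left out, and spots with outlier flags were treated as missing. No probe was saturated on any array (0 on each). A probe was tested if it was well above background, by the scanner software's own call, on all 3 arrays of at least 1 group, which 105922 probes were. A probe not well above background on any array of a group has only a bound there. The text then gives "at least N-fold": the brighter group's mean against the dim group's mean of, per array, the higher of the probe's own value and the lowest value among probes well above background. The number of arrays, 3 per group, limits the precision. Between 71.0 and 73.4% of the probes were well above background on each array.

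Of the 150305 probes, 47074 were for coding transcripts, 56748 for lncRNAs, 37853 for circRNAs, 8299 for Ensembl transcripts of a type the files do not state and 331 for other non-coding RNAs. Of 48467 probes with a RefSeq transcript, 48048 took their symbol from a reference table of the GRCm38 assembly and the rest kept the name on the array. Many of the lncRNAs carry database numbers without gene names, and at most 2 rising and 2 falling ones of these are printed by number. Positions of Agilent's own probes are on build mm9 per the file headers. The circRNA names hold positions whose build is not given in the sources used here: 97.4% of them lay inside a coding gene of GRCm38, against 35.9% after a shift by 1 Mb, so they were read as GRCm38, and 36686 lay inside exactly 1 coding gene, called the host.

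Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, knockout minus wild type, no covariate), with two-sided p-values adjusted by Benjamini-Hochberg over all tested probes and a threshold of 0.05. Errors of log2 changes are limma's standard errors (SE), and levels are means ± SD. The file headers place the 3 wild type arrays and 1 knockout array on slide 1 and the other 2 knockout arrays on slide 2. Values are therefore also given with slide as a fixed block, which leaves 3 residual degrees of freedom and rests on the knockout array of slide 1, and from slide 1 alone. Gene lists were tested with limma's camera, with a preset inter-gene correlation of 0.01 and with an estimated one, and with fry, over 18068 genes with 1 probe per gene, the tested probe of the highest mean. The p-values were adjusted over the 34 lists. Camera asks whether a list moved against other genes, fry whether its genes moved one way on balance, and fry's mixed test whether they changed in either direction.

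The lists held 713 gene names, of which 685 had a tested probe. They were NRF2 targets, NRF2 partners, other antioxidant enzymes, oxidative phosphorylation, proteasome, heat shock, the unfolded protein and integrated stress response, immediate early genes, circadian clock, glucocorticoid response, inflammation, interferon response, glutamatergic synapse, GABA synapse, monoamine signalling, lipid and cholesterol synthesis, chromosome 2 neighbours of Nfe2l2, known lncRNAs, and markers of 16 cell types or regions. Nfe2l2 and the list of NRF2 targets are always reported, the targets as a group and only in part by name. Beyond these, the text names up to 10 coding genes per direction, and up to 4 lncRNAs and 4 circRNAs, with the largest changes past the threshold and no overlap between the groups. Where fewer passed, the places were filled by the smallest unadjusted p without overlap, and these are said not to have passed. Gene symbols that are only model numbers were passed over, and of other lists up to 4 members of smallest unadjusted p may be named. The groups, tests, lists, naming rule and alternatives were fixed before the data were examined. The tests of Rbm45, of windows of neighbouring genes and of probe GC content, given at the end, were not part of that plan.

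The steps were tested on simulated data: of 200 probes changed among 105922, limma called 28 of 67 changed by 1 on the log2 scale, 61 of 67 changed by 2 and 63 of 66 changed by 4, with 4 false calls among 156. A simulated list shifted by −0.5 gave an adjusted p = 2.23e-41 in camera with the preset correlation and 0.0588 with an estimated correlation. The simulated probes varied independently and had no slide effect, while the estimated correlation in the real lists reached 0.58. These figures therefore check the steps and do not measure the false calls in the real data. Alternatives were normexp background correction with an offset of 50, quantile and median scaling, the authors' value table, other filters and flags, blocks for slide and replicate number, other variance models, array weights, other thresholds and each array left out in turn. Tables were handled in R with version 1.17.8 of the package data.table and in Python 3.11.15, and plots were drawn with matplotlib 3.10.9.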

Results

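RNA from the prefrontal cortex was measured in 3 wild type and 3 Nrf2 knockout samples of male ICR mice aged 3 to 4 months, on 1 array each. The comparison asks which coding, long non-coding and circular RNAs differ in cortex without Nrf2. The 75th percentile of the processed signal was 279, 280.3 and 278 in wild type and 269, 248 and 245 in the knockout. The arrays did not separate by genotype alone. On the first principal component, with 52.2% of the variance, the 3 wild type arrays lay at −70.7, −54.8 and −49.0, knockout 1 at −25.8, and knockouts 2 and 3 at 100.7 and 99.5. Knockout 1 shared slide 1 with the wild type arrays, and knockouts 2 and 3 were on slide 2, whose arrays had median local backgrounds of 19 and 18 against 23 to 24 on slide 1. Wild type 1 stood apart on the second component, at 93.6, with knockout 1 at −21.5 and wild types 2 and 3 at −43.4 and −44.0. It also had 186 probes with an outlier flag against 13 to 36 elsewhere.

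**Figure D1:**
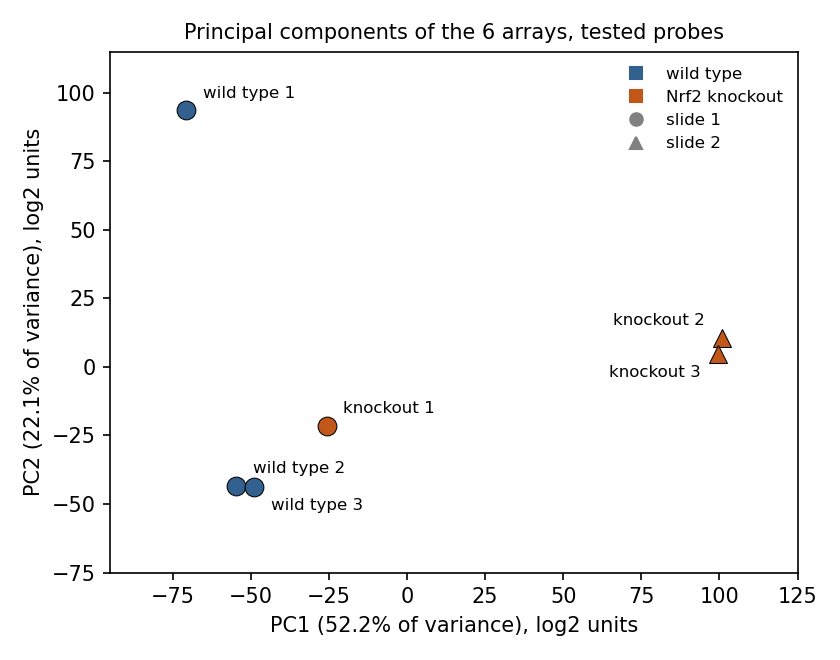
Principal components of the 6 arrays over the tested probes, PC1 (52.2% of the variance) against PC2 (22.1%), in log2 units. Colours give the genotype and shapes the slide, and the 2 knockout arrays of slide 2 lie at 100.7 and 99.5 on PC1, with the other 4 arrays between −70.7 and −25.8.

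Nfe2l2, the gene for Nrf2 itself, was far lower in every knockout sample. Of its coding probes, called A, B and C here, probe A measured a normalised log2 signal of 0.41 ± 0.072 (SD, n = 3) in wild type and −3.66 ± 0.18 (n = 3) in the knockout, a log2 fold change of −4.08 (SE 0.12, limma adjusted p = 6.13e-04). Probes B and C were not well above background in the knockout. Probe B, at chromosome 2, 75513771 to 75513830 on build mm9, was at least 81.5-fold lower there (adjusted p = 0.00907), and probe C, at 75513917 to 75513976, at least 65.6-fold lower (adjusted p = 4.78e-06). A circular RNA from inside the gene, at chromosome 2, 75675899 to 75676200 on the minus strand of GRCm38, was at least 10.1-fold lower and was likewise not well above background in any knockout sample (adjusted p = 7.17e-04). A probe for a non-coding transcript variant of Nfe2l2 gave −0.34 (SE 0.19, adjusted p = 0.393). The labels do not give the deleted part, and a probe outside it checks nothing.

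For probes A, B, C and the circRNA, the adjusted p-values with slide as a block were 0.0137, 1.77e-04, 1.77e-04 and 0.00682, and within slide 1 alone 0.0451, 0.00633, 0.00633 and 0.0213. Over all alternatives they ranged from 1.67e-05 to 0.0519, 1.55e-06 to 0.134, 5.30e-07 to 0.00633 and 2.43e-04 to 0.0519. Normexp background correction, with its offset of 50, gave smaller log2 changes of −2.42, −3.49, −3.31 and −1.06 for Nfe2l2 probes A, B, C and the circRNA, short of the bounds given above for the last 3. Probe B lost its call without wild type 2, wild type 3, knockout 2 or knockout 3 (adjusted p = 0.12, 0.108, 0.0697 and 0.0694).

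**Figure D2:**
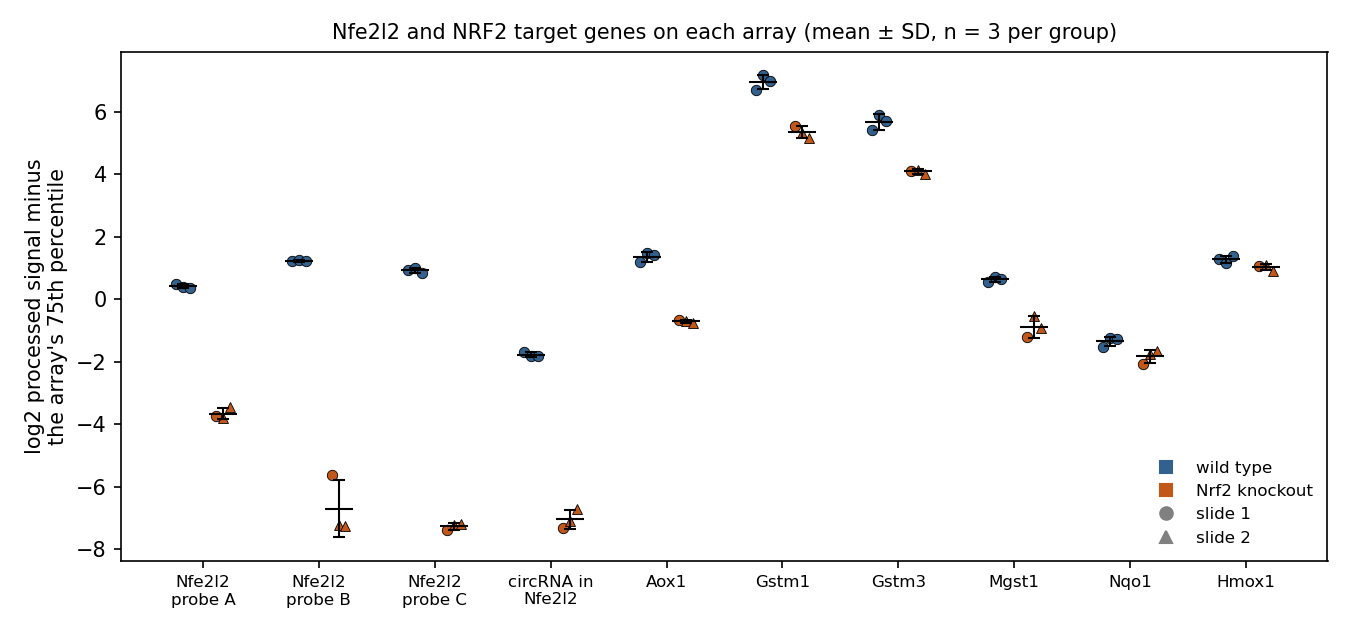
Normalised log2 signal of Nfe2l2 probes, of the circRNA inside Nfe2l2 and of 6 NRF2 target genes on each array, with the mean and SD of 3 arrays per group as black marks; circles are slide 1 and triangles slide 2. Probe A has a log2 fold change of −4.08, and probes B, C and the circRNA were not well above background in the knockout.

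Beyond Nfe2l2, few single RNAs separated the genotypes past the threshold: the RNA-binding protein gene Rbm45 and the ciliary gene Ribc2 rose at 1 probe each, and the aldehyde oxidase gene Aox1 fell. Another Rbm45 probe measured lower, and the rise of Ribc2 has a bound of only 1.1-fold. In all, 10 of 105922 probes changed, 3 higher and 7 lower in the knockout, of which 4 lie in Nfe2l2. They comprised 7 coding probes, 2 lncRNAs and 1 circRNA, while limma called 0 of 4693 probes for Ensembl transcripts (860 at an unadjusted p under 0.05) and 0 of 240 for other non-coding RNAs (43 unadjusted). At an unadjusted p under 0.05 there were 15944 probes, 15.1% against 5% by chance, with 6474 higher and 9470 lower. The groups did not overlap in 21.6% of probes, against 10% by chance. Slide as a block left 7 probes past the threshold, 5 of them among the 10, and 5.69% had an unadjusted p under 0.05. On slide 1 alone, 4 probes passed, all in Nfe2l2. The count depended on every array: it was 50 without wild type 1, 6 without wild type 2, 5 without wild type 3, 13558 without knockout 1, 6 without knockout 2 and 5 without knockout 3. Without knockout 1 all wild type arrays are on slide 1 and all knockout arrays on slide 2, so in that fit, here and for each class below, slide and genotype cannot be told apart.

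Among coding genes, Rbm45, which encodes an RNA-binding protein, rose 8.52-fold at 1 probe, from −3.18 ± 0.13 (SD, n = 3) to −0.086 ± 0.15 (n = 3) on the log2 scale (log2 fold change 3.09, SE 0.12, adjusted p = 0.00218). That probe is annotated to chromosome 2, 76218588 to 76221536 on mm9, on the same chromosome as Nfe2l2. Another Rbm45 probe measured −0.89 (SE 0.13, adjusted p = 0.275), so the probes of this gene disagree in direction. At its tested probe Ribc2, a gene for a microtubule protein of cilia, was not well above background in wild type and was at least 1.1-fold higher in the knockout (adjusted p = 0.0087). A second Ribc2 probe, not tested, was well above background in 1 of 3 wild type and 2 of 3 knockout samples. Aox1, an aldehyde oxidase and a known NRF2 target, fell at both probes that passed, by 2.06 (SE 0.11) and 1.96 (SE 0.14) on the log2 scale, with adjusted p = 0.0087 and 0.0381. Its level at the first was 1.35 ± 0.15 (SD, n = 3) in wild type and −0.71 ± 0.054 (n = 3) in the knockout, 4.18-fold lower.

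Rbm45 kept its call with slide as a block (adjusted p = 0.0152, 0.149 within slide 1, range over all alternatives 1.33e-04 to 0.149), and its value was 1.88 with normexp. Ribc2 and both Aox1 probes did not (0.0685, 0.0841 and 0.123, and within slide 1 0.199, 0.28 and 0.28, with ranges from 0.00103 to 0.213, 3.76e-04 to 0.28 and 0.00277 to 0.319). The differences kept about their size under the block, at −2.02 (SE 0.15) and −2.08 (SE 0.18) for Aox1, and the errors grew, so the lost calls do not show an effect of the slides. Ribc2 lost its call without wild type 2, wild type 3 or knockout 3 (adjusted p = 0.111, 0.108 and 0.0844). The first Aox1 probe lost it without wild type 2, wild type 3, knockout 2 or knockout 3 (0.0899, 0.108, 0.0953 and 0.0844), as did the second (0.225, 0.213, 0.244 and 0.0878).

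Further coding genes had no overlap between the groups but did not pass the threshold. On the higher side, Tcf7l1, a transcription factor of Wnt signalling, measured 4.42 (SE 0.37, adjusted p = 0.083), with 4.29 at a second probe and −0.073 at another, and it was well above background in 2 of 3 wild type samples. Dnah6, a dynein heavy chain of motile cilia, measured 2.35 (SE 0.21, adjusted p = 0.0841). Chmp3, a subunit of the ESCRT-III membrane-remodelling complex, measured 1.11, with 0.56 and −0.50 at its other probes. D3Ertd751e measured 1.16, with 0.74 and 0.19 at its other tested probes, Fam181a 0.90 and 0.76, H2al1m 0.65, with 0.585 and 0.004 at its others, and Zar1l 0.68. Tbx19, a T-box transcription factor, was at least 2.22-fold higher (0.43 with normexp, short of that bound). At the first probe named, adjusted p-values from Chmp3 to Tbx19 were 0.204 to 0.259. On the lower side, the glutathione S-transferases Gstm3 and Gstm1 measured −1.58 (SE 0.14, adjusted p = 0.0841) and −1.61 (SE 0.16, adjusted p = 0.109). These are close paralogs, and signal shared between their probes was not tested. Another Gstm3 probe, left out of the test, was not well above background in any sample, at −6.81 in wild type and −6.92 in the knockout. The fall of Gstm3 therefore rests on 1 probe. Aox3, another aldehyde oxidase, measured −1.02, with −0.52 at its other probe, and Bdh2, a dehydrogenase, −0.93 and −0.98. A further Bdh2 probe, left out of the test, averaged −4.595 in wild type and −4.603 in the knockout. It was well above background in 2 of 3 samples of each genotype. The chemokine Ccl8 measured −4.81 (SE 0.50), −4.96 at a second probe, and was well above background in 2 of 3 knockout samples. At 1 probe each, Atp8b4, Slc9a4 and Nipal1 were at least 1.57-fold, 1.4-fold and 1.23-fold lower, but normexp gave only −0.092, −0.16 and −0.059, short of these bounds. Probes left out of the test did not repeat the fall: 2 for Slc9a4 averaged −4.86 and −5.07 in wild type and −4.88 and −5.07 in the knockout, and 1 for Atp8b4 −5.42 and −5.24, each well above background in only some samples. Adjusted p-values of these 6 at the first probe named were 0.0841 to 0.13.

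Over the 39126 coding probes, 7 passed, 2 higher and 5 lower, and 4328 (11.1%) had an unadjusted p under 0.05. With slide as a block the unadjusted share was 4.61%, under the 5% given by chance. Groups did not overlap in 19.1% of coding probes, against 10% by chance. The slide block left 4 coding probes, and slide 1 alone 3. The number was 26 without wild type 1, 3 without wild type 2, 3 without wild type 3, 2769 without knockout 1 and 4 without knockout 3.

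The lncRNAs NONMMUT087000 and NONMMUT082060 were the ones past the threshold. NONMMUT087000 was at least 1.26-fold lower in the knockout (adjusted p = 0.00784) and NONMMUT082060 at least 1.49-fold higher (adjusted p = 0.0381), and each was not well above background in the dimmer genotype. With normexp they measured −0.16 and 0.30, short of these bounds. Among those that did not pass, NONMMUT114173 was at least 2.74-fold lower (adjusted p = 0.0728), 2 others on the lower side had adjusted p = 0.0907, and of 3 on the higher side, with adjusted p = 0.0728 to 0.0841, 1 measured 2.35 (SE 0.19) and the others, not well above background in wild type, were at least 1.72-fold and 2.38-fold higher. Normexp gave less than the bound for all 3 given here (−0.38, 0.26 and 0.43). Of 27310 lncRNA probes, 5583 (20.4%) had an unadjusted p under 0.05, with 1615 higher and 3968 lower, and 22.8% had no overlap between the groups, against 10% by chance. With slide as a block the unadjusted share was 9.59%, with 1234 higher and 1386 lower. Neither of the pair passed with slide as a block (0.0615 and 0.195, and 0.235 and 0.5 within slide 1, ranges over all alternatives 0.00127 to 0.263 and 0.00234 to 0.5), though the differences kept about their measured size, with SEs of 0.16 and 0.24 against 0.13 and 0.18. The block called 1 lncRNA, NONMMUT129309 (3.26, SE 0.11, adjusted p = 0.00682). Over the 6 arrays it measured 0.895 (SE 0.93, adjusted p = 0.622), with knockout 1 at −0.67 and the other knockouts at −4.23 and −4.20, near the wild type mean of −3.93. Within slide 1, limma called 0 lncRNAs (2699 unadjusted). NONMMUT087000 lost its call without wild type 3, knockout 2 or knockout 3 (0.0509, 0.0629 and 0.0694), and NONMMUT082060 without wild type 1, wild type 2, knockout 2 or knockout 3 (0.0615, 0.234, 0.244 and 0.274). The lncRNA count was 11 without wild type 1, 1 without wild type 3, 5005 without knockout 1, and 0 in limma without knockout 2 or without knockout 3, where 8082 and 7729 probes of all classes had an unadjusted p under 0.05.

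The circRNA from inside Nfe2l2 was the only one of 34553 tested circRNAs to pass, at least 10.1-fold lower as given above. Other circRNAs without overlap did not pass. On the lower side, circRNAs hosted by E2f5, a cell cycle transcription factor (chromosome 3, 14587310 to 14588314, minus strand), Pdk1, a pyruvate dehydrogenase kinase (chromosome 2, 71880039 to 71897760, plus strand), and Dpyd, a pyrimidine-degrading enzyme (chromosome 3, 118915205 to 119141985, plus strand), measured −1.17, −0.87 and −1.20 (adjusted p = 0.0997, 0.102 and 0.178). The first of these was well above background in 2 of 3 knockout samples. On the higher side, circRNAs hosted by Cercam (chromosome 2, 29868978 to 29871392, plus strand) and Rbm20 (chromosome 19, 53850102 to 53864389, plus strand) were at least 1.52-fold and 1.33-fold higher, and measured 0.19 each with normexp, short of these bounds. Those hosted by Pigs (chromosome 11, 78335427 to 78336830, plus strand) and Wdfy3 (chromosome 5, 102009789 to 102045448, minus strand) measured 0.74 and 0.69, and these 4 had adjusted p = 0.0907 to 0.238. All positions are on GRCm38.

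At an unadjusted p under 0.05 there were 5130 circRNAs (14.8%), 3004 higher and 2126 lower, and 23.3% had no overlap, against 10% by chance. Among the 470 that also had a 2-fold change, the direction was the opposite, with 22 higher and 448 lower. The unadjusted share of circRNAs fell to 3.49% with slide as a block, under the share given by chance, with 701 higher and 506 lower. The slide block left 2 circRNAs, the one inside Nfe2l2 and one hosted by Bmpr1b, a BMP receptor gene (chromosome 3, 141981921 to 142021519, minus strand; 3.28, SE 0.14, adjusted p = 0.0192), named after its value was seen. Over the 6 arrays the latter measured 1.26 (SE 0.80, adjusted p = 0.443), and within slide 1 only the Nfe2l2 circRNA passed. The Bmpr1b circRNA lay at −1.09 in knockout 1 and at −4.15 and −4.10 in the other knockouts, near its wild type mean of −4.37. Its call with the block thus rests on knockout 1. The circRNA count was 6 without wild type 1 and 5020 without knockout 1.

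Changes of circRNAs correlated only weakly with changes of their host genes. Across 33460 circRNAs of 6524 host genes, the log2 fold changes correlated at Pearson's r = 0.072 and Spearman's rho = 0.11, and 55.0% had the same sign. The circRNA of Nfe2l2, which was lower together with its host, was left out. Few RNAs of either class passed the threshold, so noise may hide a relation, and the weak correlation does not show that there is none. Genes are not independent replicates, so no p is given. The other 9 splits of the same arrays gave r between 0.0449 and 0.198 with a median of 0.103, rho between 0.0579 and 0.34, and a same-sign share between 47.8 and 62.4%. The correlation was 0.123 with slide as a block, within slide 1 0.124, and without wild type 1 0.127.

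Genes known as NRF2 targets were lower as a group in the knockout, led by the detoxification enzymes Aox1, Gstm3, Gstm1 and Mgst1. Of 45 measured targets, 35 lay below 0 and 10 above, with a median log2 fold change of −0.076 and a mean of −0.26 (camera adjusted p = 5.40e-04, but 0.887 with an estimated correlation, where the call was lost). The slide block gave a median of −0.15 (adjusted p = 1.44e-04, and 0.868 with an estimated correlation), and within slide 1 the adjusted p was 2.40e-04. Over all tested probes 1 target fell, Aox1, and adjusted over the list alone 4 fell, Aox1, Gstm3 (−1.58), Gstm1 (−1.61) and the microsomal glutathione S-transferase Mgst1 (−1.53, SE 0.18), and 0 rose in limma. Signal shared between the Gstm3 and Gstm1 probes was not tested, so these may not be separate falls. At an unadjusted p under 0.05 there were 11 lower and 0 higher. Targets that did not pass included Gstm2 at −0.64 (SE 0.18), the quinone reductase Nqo1 at −0.48 (SE 0.14), the epoxide hydrolase Ephx1 at −0.35 (SE 0.11), Ptgr1 at −0.47, Blvrb at −0.34, malic enzyme Me1 at −0.28 and thioredoxin Txn1 at −0.25. The glutathione synthesis genes Gclm and Gclc measured −0.28 (SE 0.15) and −0.12 (SE 0.12), and heme oxygenase Hmox1 −0.25 (SE 0.10). The sulfiredoxin gene Srxn1 measured 0.19 (SE 0.13) and −0.037 with slide as a block. The cystine transporter Slc7a11 measured −0.24 (SE 0.27) and 0.054 without knockout 1, and the thioredoxin reductase Txnrd1 −0.013 (SE 0.12) and 0.038 with median scaling.

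For the NRF2 targets, the adjusted p ranged over all alternatives from 1.22e-09 to 0.887. Fry gave an adjusted p = 0.0909 for a move one way and 4.82e-04 for changes in either direction. The median was −0.12 without wild type 1 (adjusted p = 1.62e-04) and −0.049 without knockout 1 (adjusted p = 0.0341).

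Inflammation and interferon genes were lower as groups as well, and so were markers of the meninges. With an estimated correlation all 3 calls were lost (adjusted p = 0.223, 0.887 and 0.887). Of 29 inflammation genes, 25 lay below 0, with a median of −0.25 (adjusted p = 1.52e-04). Adjusted over the list alone 5 fell and over all genes 0 did (9 lower at an unadjusted p under 0.05 in limma). The 5 include complement C4b (−0.89, SE 0.17), the endotoxin receptor Tlr4 (−0.60, SE 0.12) and the chemokines Ccl2 (−0.77, SE 0.18) and Cxcl10 (−2.63, SE 0.62). Of 29 interferon response genes, 26 lay below 0, with a median of −0.20 (adjusted p = 2.66e-04). Adjusted over the list alone 1 fell, the immunoproteasome subunit Psmb8 (−0.79, SE 0.13), and over all genes 0 did (9 lower unadjusted in limma). The peptide transporter Tap1 (−0.48), the transcription factor Irf1 (−0.31) and the antiviral Oas2 (−0.81) did not pass. All 14 markers of meninges and fibroblasts lay below 0, with a median of −0.40 (adjusted p = 1.78e-04). Adjusted over the list alone 5 fell, and over all genes 0 (7 lower unadjusted in limma), among them matrix Gla protein Mgp (−0.79, SE 0.21), the retinaldehyde dehydrogenase Aldh1a2 (−0.64, SE 0.19), prostaglandin D synthase Ptgds (−0.34, SE 0.099) and the sulfate transporter Slc13a4 (−0.47, SE 0.15). Of the 17 microglia markers, 16 lay below 0, with a median of −0.069 (adjusted p = 0.338), and Tyrobp measured −0.20.

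The medians of the inflammation, interferon and meninges lists with slide as a block were −0.27, −0.23 and −0.64 (adjusted p = 0.00827, 0.0877 and 8.36e-07, and with an estimated correlation 0.868, 0.986 and 0.868), and within slide 1 the adjusted p-values were 0.0147, 0.111 and 1.34e-06. Over all alternatives these ranged from 1.37e-06 to 0.223, 3.31e-08 to 0.887 and 6.07e-08 to 0.887. For a move one way, fry gave adjusted p = 0.00408 for the inflammation list and 0.533 for the other two. The interferon median was −0.35 without wild type 3, and that of the meninges −0.25 without wild type 1 (adjusted p = 0.0234).

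Lists of the glutamatergic synapse, deep layer neurons, oxidative phosphorylation and blood cells were slightly higher as groups. With an estimated correlation all 4 calls were lost (adjusted p = 0.887, 0.887, 0.928 and 0.887), and with slide as a block the oxidative phosphorylation median turned to −0.045. Of 32 genes of the glutamatergic synapse, 25 lay above 0, with a median of 0.085 (adjusted p = 0.0176). The scaffold genes Dlgap1 and Shank1 and the AMPA receptor subunit Gria2 measured 0.34, 0.18 and 0.17, while the synaptic vesicle gene Syn1 measured −0.76 (SE 0.32), and 0.027 with slide as a block. Of 12 deep layer markers, 11 lay above 0, with a median of 0.10 (adjusted p = 0.0387), among them Rprm (0.37), Syt6 (0.32), Etv1 (0.18) and Tle4 (0.15). Their lowest values over all alternatives were 0.22, 0.12, 0.029 and 0.042. The mean of the deep layer list was 0.11, but −0.046 with slide as a block, where the median was 0.031. Of 49 oxidative phosphorylation genes, 37 lay above 0, with a median of 0.049 (adjusted p = 0.0387), among them Ndufs8 (0.30), Sdha (0.25) and Ndufa2 (0.17). Of 14 blood cell markers, 9 lay above 0, with a median of 0.18 (adjusted p = 0.0266), led by the globins Hbb-bt (0.79, SE 0.23), Hbb-b2 (0.55), Hba-a2 (0.53) and Hba-a1 (0.44). In limma 0 members of these 4 lists passed, over all genes or adjusted over the list alone, and at an unadjusted p under 0.05 there were 0 synaptic, 2 deep layer and 0 oxidative phosphorylation genes, and 5 higher and 1 lower blood marker.

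With slide as a block the medians of the glutamatergic, deep layer, oxidative phosphorylation and blood lists were 0.013, 0.031, −0.045 and 0.27 (adjusted p = 0.0675, 0.569, 0.998 and 5.70e-04, the last 0.868 with an estimated correlation), and within slide 1 the adjusted p-values were 0.0961, 0.696, 0.941 and 0.00103. Ranges over all alternatives were 6.59e-04 to 0.887, 0.0289 to 0.887, 0.00991 to 0.998 and 2.73e-05 to 0.887. The glutamatergic median was 0.15 without wild type 1 (adjusted p = 0.00335) and 0.11 without knockout 1 (0.0957). The deep layer median was 0.089 without wild type 1 (0.151), 0.17 without wild type 3, 0.19 without knockout 1 (0.0569) and 0.10 without knockout 3 (0.127). The blood median was 0.15 without wild type 1 (0.201), 0.27 without wild type 3 (0.0811), 0.18 without knockout 1 (0.367) and 0.31 without knockout 2. For oxidative phosphorylation it was 0.054 without wild type 1 (0.101), 0.0078 without wild type 2 (0.187), 0.075 without wild type 3 (0.0209), 0.10 without knockout 1 (0.00991), 0.025 without knockout 2 (0.0725) and 0.016 without knockout 3 (0.133).

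In all, 8 of the 34 lists passed with the preset correlation, 0 in camera with an estimated correlation (1 at an unadjusted p under 0.05, inflammation), 4 with slide as a block and 5 without wild type 1 or knockout 1. The other lists did not pass. In the simulation, camera with an estimated correlation also missed a list shifted by −0.5 (adjusted p = 0.0588). A call lost with that setting therefore does not show that a list was unchanged. Splits of the arrays that mix the genotypes gave up to 11 lists with the preset correlation, so the number that passed does not set the genotypes apart. Among stress and signalling lists, the medians and adjusted p-values were −0.019 and 0.794 for the 12 NRF2 partners (Maff −0.66), 0.085 and 0.227 for 26 other antioxidant enzymes (Gpx3 0.56), 0.018 and 0.301 for 32 proteasome genes, 0.033 and 0.435 for 15 heat shock genes (Hspb1 −0.33), 0.015 and 0.42 for 20 genes of the unfolded protein and integrated stress response, and 0.013 and 0.84 for 23 immediate early genes (Npas4 0.71). They were 0.05 and 0.301 for 19 circadian clock genes, −0.067 and 0.42 for 15 glucocorticoid response genes (Sult1a1 −0.78, Fkbp5 −0.40), 0.046 and 0.172 for 21 GABA synapse genes (Slc32a1 0.30), −0.099 and 0.252 for 31 monoamine genes (Drd2 −0.43, and Slc6a4 −0.88, well above background in 1 of 3 knockout samples), and 0.0069 and 0.938 for 25 lipid and cholesterol genes.

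Of 45 measured chromosome 2 neighbours of Nfe2l2, with a median of −0.041 (adjusted p = 0.938), Ttc30a2, a gene of ciliary transport, rose by 0.45 (SE 0.088) adjusted over the list alone, and the second Rbm45 probe fell by 0.89. Zfp385b and Pde11a measured 0.34 and 0.39 and did not pass. Fry's test for changes in either direction gave an adjusted p = 4.15e-04 for this list. For 25 known lncRNAs the median was 0.0071 and the adjusted p 0.938 (H19 −1.28, and from −1.71 to −0.42 over all alternatives). Among cell type and region markers, medians and adjusted p-values were 0.025 and 0.503 for 10 excitatory neuron genes, 0.077 and 0.338 for 10 upper layer genes, −0.042 and 0.807 for 20 inhibitory neuron genes, −0.0014 and 0.991 for 15 astrocyte genes (Gfap −0.49), −0.059 and 0.503 for 17 oligodendrocyte genes and 0.07 and 0.252 for 11 precursor genes (Bcas1 0.51). They were 0.0016 and 0.938 for 15 endothelial genes (Ly6c1 −0.36), 0.051 and 0.629 for 11 mural cell genes (Tagln −0.40, Acta2 0.32), −0.095 and 0.252 for 15 choroid plexus genes (Kcnj13 −0.55, with fry's test for changes in either direction at 0.0316), 0.048 and 0.94 for 15 striatal genes (Adora2a −0.53), 0.26 and 0.126 for 11 olfactory bulb genes and −0.11 and 0.503 for 12 hippocampus genes (Pou3f1 −0.55). The mean had the opposite sign to the median for lipid (−0.033), known lncRNA (−0.063), endothelial (−0.013) and striatal (−0.046) genes. Camera's direction opposed the median for the lipid, striatal, astrocyte and chromosome 2 lists, and the mean for the known lncRNA, endothelial, astrocyte and chromosome 2 lists.

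**Figure D3:**
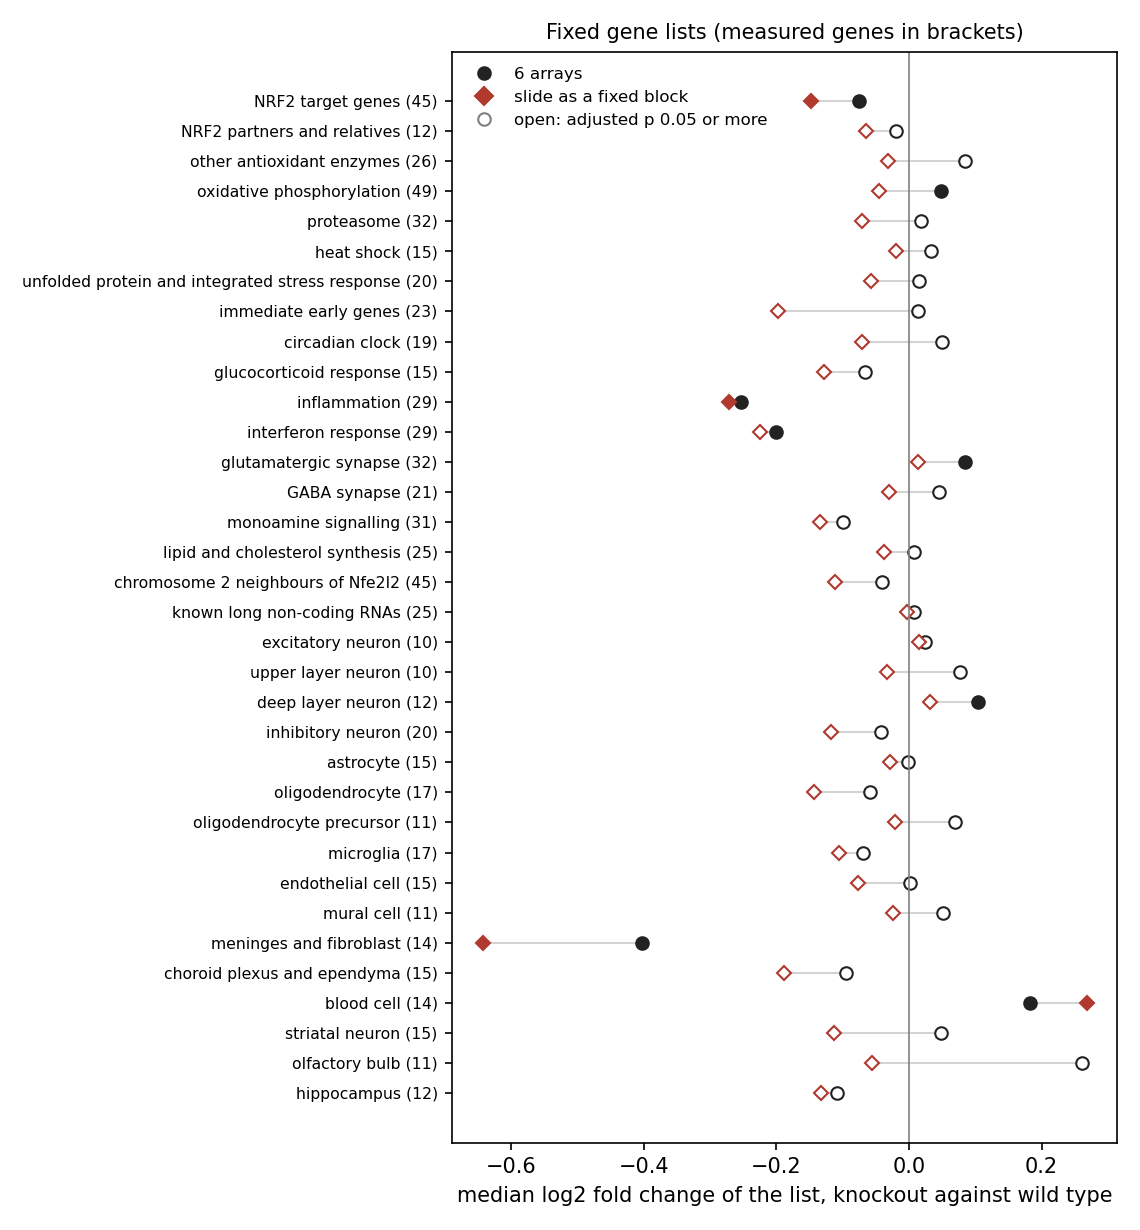
Median log2 fold change, knockout against wild type, of each of the 34 gene lists over the 6 arrays (circles) and with slide as a fixed block (diamonds), with open marks where the adjusted p was 0.05 or more. The 14 meninges and fibroblast markers lie at −0.40 and −0.64, and oxidative phosphorylation lies at 0.049 and −0.045, on opposite sides of 0.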

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

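No alternative was added after the data were seen. Direction held for the Nfe2l2 knockout check (log2 fold changes from −4.18 to −4.01 with each array left out) and for the NRF2 target list in every alternative. The NRF2 target list was past the threshold in 20 of 21, with a median of −0.076 and adjusted p = 0.887 with an estimated correlation, which left 0 gene lists past threshold in camera against 8 (1 at an unadjusted p under 0.05), and medians from −0.12 to −0.049 with each array left out. Among the other 7 lists that passed, 107 of 147 values kept their call and 39 lost it. Oxidative phosphorylation list values reversed once, to −0.045 with slide as a fixed block. Of 1917 values for 102 named probes, 1734 kept their side of the threshold, 55 lost a call, 117 gained one and 11 reversed. Reversed values were 0.038 (median scaling), 0.036 (array weights) and 0.00 (the authors' value table) for Txnrd1, whose range was −0.12 to 0.063 with each array left out, −0.42 to 0.054 for Slc7a11 with each left out, −0.037 for Srxn1 and 0.027 for Syn1 both with slide as a fixed block and on slide 1 alone.

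For all probes changed (10), the count was 16 with normexp, 21 with trended and robust eBayes, 19 with adjustment within each class, 4 on slide 1 alone and 4 with the filter for all 6 arrays (15425 unadjusted). Array quality weights, 0.29 for knockout 1 and 0.848 to 1.68 for the others, gave 10819, and an unadjusted p under 0.05 with a 2-fold change gave 1711. Leaving out 1 array gave 5 to 13558, the highest probe counts here and below being those without knockout 1, where slide and genotype coincide. For coding probes changed (7), the counts were 14 with normexp, 14 with trended and robust eBayes, 2355 with weights, 388 unadjusted, 3 on slide 1 alone, 4 with slide as a fixed block, 4 with the stricter filter, and 3 to 2769 with 1 array left out. For lncRNA probes changed (2), they were 0 with normexp, 1 with quantile scaling, 4 with median scaling, 5 with adjustment within the class, 4118 with weights, 734 unadjusted, 0 on slide 1 alone, 1 with slide as a fixed and 1 as a random block, 1 with the authors' table, 0 with the stricter filter, and 0 to 5005 with 1 array left out. In limma 5583 lncRNAs had an unadjusted p under 0.05 in the main fit and 2699 on slide 1 alone, and of all classes 18801 probes did with normexp. For circRNA probes changed (1), they were 3715 with weights, 470 unadjusted, 2 with slide as a fixed block, 0 with the stricter filter, and 1 to 5020 with 1 array left out. Gene lists past threshold (8) were 5 with the mean of a gene's probes, 5 with normexp, 4 with slide as a fixed block, 4 on slide 1 alone, and 5 to 7 with 1 array left out. The circRNA against host gene correlation (0.072) was 0.123 with slide as a fixed block, 0.124 on slide 1 alone, and 0.0552 to 0.127 with 1 array left out. The looser threshold calls more and slide 1 alone has fewer arrays by construction. For the other settings the cause was not tested.

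The replicate numbers that the genotypes share gave no sign of pairing the samples. Deviations from the group means correlated at −0.013, −0.05 and 0.038 for equal numbers, and not every sample correlated best with its own number. Knockout 1 was on another slide than the other knockouts and wild type 1 stood apart, so such correlations cannot exclude a pairing. With the replicate number as a block, 2 probes changed, 2 coding, 0 lncRNA and 0 circRNA (14057 of all classes at an unadjusted p under 0.05 in limma). The Nfe2l2 knockout check then gave −4.08 with adjusted p = 0.0519, in a range of 1.67e-05 to 0.0519 over its alternatives, in a fit with fewer residual degrees of freedom. Signal over background limits what can be said of the tested Ribc2 probe and the lncRNAs that passed, which were not well above background in 1 genotype.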

Other observations

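The test of the genes beside Dnah6 was chosen only after the result was seen. The tests of Rbm45 concern a gene picked for its rise in the main fit.

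Several genes beside Dnah6 on chromosome 6 differed between the genotypes at an unadjusted p under 0.05, though none passed the adjusted threshold. Thnsl2, a threonine synthase-like gene, measured 1.53 (SE 0.23) on the log2 scale, Elmod3 0.75 (SE 0.13), and Eif2ak3, the kinase PERK of the unfolded protein response, 0.44 (SE 0.09), each higher in the knockout. Retsat, a retinol saturase, measured −1.33 (SE 0.38) and Reg1 −2.24 (SE 0.58). Adjusted p-values of these 5 were 0.264 to 0.307, and with slide as a block the values were 1.32, 0.52, 0.32, −0.85 and −0.80. Most of the lower genes of this window shrank with that block, and 5 of the 8 then lay between −0.18 and 0.04. These genes were named after their values were seen. Tcf7l1, Chmp3 and Dnah6, given above, lie in the same neighbourhood.

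Many more RNAs differed between the knockout samples of the 2 slides than between the genotypes. With both terms in the limma fit, 4281 of 105917 probes had a slide term past the threshold, 376 higher and 3905 lower on slide 2, and lncRNAs (1680) and circRNAs (1621) outnumbered coding probes (734). This term sets knockouts 2 and 3 against knockout 1 alone, so it does not part the slides from the samples.

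The share of probes at an unadjusted p under 0.05 was 15.1%, against 5% by chance. Scaling of the arrays and probe GC content were argued against as the cause, since the share was 15.9% with quantile normalization and 14.7% after a smooth GC trend was taken out of each array, which left 10 probes past the threshold. With slide as a term the share was 5.69%, as a difference between the slides would give. That fit rests on knockout 1 and 3 residual degrees of freedom, with a median SE of 0.144 against 0.128. A genotype effect stronger in knockouts 2 and 3 therefore stays open too.

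Rbm45 rose at 1 probe, and in knockout 1, on the slide of the wild type arrays, it lay 3.13 above the highest wild type array on the log2 scale, which argues against the slides as the cause. The other tested Rbm45 probe measured −0.89, in line with a sequence variant or hybridisation at a single probe, or with a shift between transcript forms, which was not tested. DNA linked to Nfe2l2 that differs between the groups is another candidate explanation: the median absolute log2 change of 44 listed chromosome 2 neighbours was 0.162, against 0.109 over 10000 random lists of similar signal, the 99th percentile. Both stay open.

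Windows of neighbouring genes also ranked high. The 50 coding genes nearest to Nfe2l2 had a mean absolute moderated t of 1.66, the 97.1th percentile of 16430 windows, with 7 higher and 3 lower at an unadjusted p under 0.05. The 95th percentile of the windows was 1.61. Rbm45 (−0.89, SE 0.13) is among these 50 genes, and the mean without it was not computed, so the rank may rest on that gene. The 50 genes nearest to Dnah6, with Dnah6, Tcf7l1 and Chmp3 left out, reached 1.86 and the 99.3th percentile, with 7 higher and 8 lower. With slide as a block the percentiles were 98.8 and 98.7. Stretches of DNA that differ between the outbred animals of each group may be behind both, which stays open. The highest window lay around Olfr1428 on chromosome 19 (2.31, 3 higher and 18 lower). A window around C4b, a gene of the inflammation list, on chromosome 17 reached 1.81, with 2 higher and 11 lower. Its percentile was 99.1, and 91.4 with slide as a block. Whether differing DNA there lowers members of the inflammation or interferon lists was not tested.

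The 6 arrays can be split in 10 ways, too few for a share under 0.05. For the counts of changed probes, 1 of the 10 splits, the real one, gave as many: 10 over all probes against at most 2 in the others, 7 against 1 for coding probes, 2 against 0 for lncRNAs and 1 against 0 for circRNAs. The real counts include the probes in Nfe2l2 itself, among them the only circRNA. The background filter of the real groups was also kept for every split, which favours the real one. For gene lists, 3 of the 10 splits gave at least the real 8, and the highest other gave 11. The number of lists past the threshold therefore does not set the real comparison apart, which limits the list calls above. One of these 3 splits, wild types 1 and 2 with knockout 1 against the rest, keeps the slide 2 arrays together and gave 9. With slide as a block the real comparison gave 4. Besides the real one, 3 splits keep the slide 2 arrays together, and they had 8.09 to 11.5% of probes at an unadjusted p under 0.05, against 1.35 to 2.52% in the 6 that part them.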
